A study of Drosophila melanogaster with 12 samples.

How the data were processed

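RNA from whole 3rd instar Drosophila melanogaster larvae was sequenced in 12 libraries, 3 in each of 4 groups. Libraries were made by a stranded mRNA method from Illumina, per the labels' protocols. The groups cross 2 genotypes with 2 diets. Control larvae carried 1 copy of a sugarbabe (sug) allele over a wild-type chromosome (sug17d/+), and mutant larvae carried the same allele over a deletion of the region, Df(2R)Exel7123. Eggs were laid over 3 h and larvae were moved after 24 h to food of 10% yeast and after another 24 h to the test food, either fresh 10% yeast (low sugar diet, LSD) or 10% yeast with 20% sucrose (high sugar diet, HSD). LSD larvae were collected 1.5 h and HSD larvae 8 h after the last transfer, and larvae that did not feed were removed at 1.5 h, so diet and time of collection cannot be told apart in any comparison of the diets. The labels give a replicate letter to each library but do not say that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical in part.

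The deposited values are raw read counts per annotated exon, 82046 exon rows by 12 libraries, with no normalization. BWA 0.5.9, HTSeq 0.6.1 and SAMtools are named in the submitters' processing notes. The genome build, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Coordinates are printed as the deposited table gives them, without naming a build, and were not mixed with those of any reference. Where exons of the same gene overlap each other, most rows hold 0: 71.3% of 16093 overlapping exons of expressed genes had 0 counts in all libraries, against 3.7% of 38524 exons without overlap. Reads in shared stretches of exons therefore appear not to have been counted, and 409 of 7803 expressed genes had under 50% of their exonic length in 1 exon only. Among the 199 genes that the naming rule selected, 16 were of this kind, and 89 overlapped the span of another gene, whose reads can be told apart only where the counting used strand. Near-identical genes, such as the amylase pair Amy-p and Amy-d, can share reads, and the split of reads between them is uncertain.

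Exon counts were summed per gene. Rows without a usable gene name (42 rows, 0.012% of counts) were left out. The 16416 gene names were kept as in the table, and 16133 matched a current symbol. Totals ran from 16112230 to 20323006 counts per library, and the 10 most abundant genes took 9.58% to 10.52% of the counts. Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the 4 groups kept 10284 genes, libraries were scaled by TMM, dispersions were estimated robustly, and a quasi-likelihood test with Benjamini-Hochberg adjustment was run for each contrast, with all 12 libraries in 1 model of 4 groups and a threshold of 0.05. Levels are TMM-scaled CPM values of edgeR, as mean ± SD over 3 libraries. The standard error of a log2 fold change is its unshrunk size divided by the square root of the F statistic.

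The design, the alternatives, the gene lists and the rule for naming genes were written before the data were examined. The rule names sug, the 5 genes with the largest rise and the 5 with the largest fall in each comparison (adjusted p under 0.05, mean of at least 4 CPM, no overlap between the libraries of the groups, the last not asked of the interaction), the 4 members with the smallest p of each list that was called or had at least 3 called members, and all members of the lists of fatty acid synthesis, of amylases and maltases and of sugar-responsive regulators. All 482 list members were found among the gene names. The 31 lists cover metabolism, digestion, hormone signalling, stress and markers of other tissues. Of these, 29 had at least 3 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with the correlation estimated from the data and fry as alternatives. The list of cuticle proteins was drawn by name and also takes in Cpr, a P450 reductase, while genes spelled Twdl are missed.

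Alternatives were other scalings (RLE, upper quartile), no filter, a filter of 5 CPM in 3 libraries, non-robust estimates, the replicate letter as a block, DESeq2 1.42.0, a test against a fold of 1.5, fits to the groups of 1 comparison, each library left out in turn, and, chosen after the data were seen, the mean level of the cuticle genes as a covariate. On simulated counts for the comparison of the genotypes on HSD, with 200 of 10284 genes changed, the test recovered 49 of 67 genes changed by 1.5-fold (73.1%), 65 of 67 changed by 2-fold (97%) and 64 of 66 changed by 4-fold (97%), with 10 unchanged genes called (5.3% of calls). In the simulated diet comparison without any change, 0 genes were called. The changed genes were drawn only from genes above a minimum expected count, so the recovery does not cover genes of few reads. Genes were simulated independently of each other, so these false calls leave out what variation shared by many genes would add. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the plots.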

Results

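Gene expression was measured in whole 3rd instar larvae labelled as null mutants of sugarbabe (sug), which encodes a zinc finger transcription factor, and in heterozygous controls, on a low sugar diet (LSD, collected at 1.5 h) and a high sugar diet (HSD, collected at 8 h). Each of the 4 groups held 3 libraries of 16112230 to 20323006 counts. Within each group, all pairs of libraries differed by more than counting noise (chi-square per degree of freedom of 9.5 to 28.03), so no pair looked like 1 library deposited again.

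The targeted gene, sug (2R, 8812072 to 8818149 in the deposited table), was lower in mutant than in control larvae on both diets, and higher on HSD than on LSD in both genotypes. On HSD, the control libraries A, B and C held 145 CPM, 134 CPM and 126 CPM, and the mutant libraries 20.9 CPM, 20.8 CPM and 24.8 CPM. On LSD, the control libraries held 32.9 CPM, 24.2 CPM and 31.8 CPM, and the mutant libraries 5.39 CPM, 6.03 CPM and 6.58 CPM. The log2 fold change of mutant against control was -2.61 ± 0.12 (SE, adjusted p = 1.35e-09) on HSD and -2.30 ± 0.13 (adjusted p = 4.85e-08) on LSD. With HSD, sug rose by a log2 fold change of 2.19 in control and 1.88 in mutant larvae, and these rises did not differ by the interaction test (-0.31 ± 0.17, adjusted p = 0.578). Nearly all counts came from exon 4 (8817289 to 8818149), and exons 1 to 3 held 0 to 5 counts per library. Exon 3 (8816469 to 8816846) lies inside exon 2 (8816365 to 8816846). Reads in their shared stretch may not have been counted, so these low counts do not show that the stretch was absent from the RNA. Where the lesion of the allele lies relative to exon 4 is not given in the sources used here, and the first exon overlaps the gene CG13319.

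**Figure D1:**
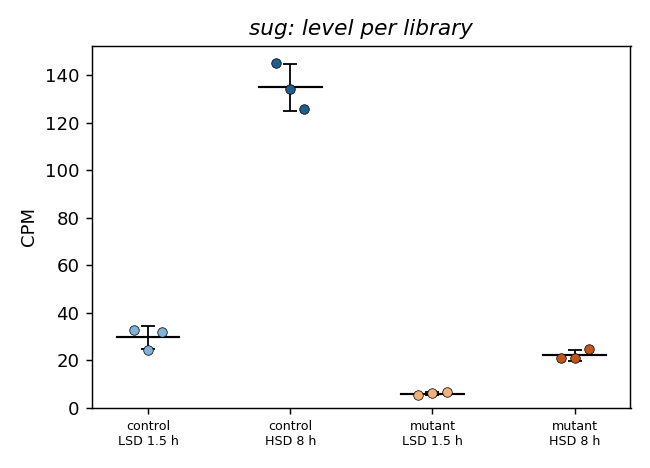
Level of sug in CPM (y axis) in each of the 12 libraries (points) by group (x axis), with bars for the mean and SD of 3 libraries. The control libraries on HSD lie between 126 and 145 CPM and the mutant libraries on HSD between 20.8 and 24.8 CPM.

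The first comparison set mutant against control larvae on the high sugar diet. Mutant larvae carried the deletion of the region, which control larvae did not. Loss of sug, loss of its neighbours and the genetic background therefore cannot be told apart in any comparison of the genotypes. Genes of starch and maltose digestion were higher in mutant larvae. Amy-p, an amylase, was at 337 CPM ± 34.2 (SD, n = 3) in mutant and 12.1 CPM ± 6.21 (SD, n = 3) in control larvae (log2 fold change 4.79 ± 0.33, adjusted p = 2.62e-05). The split of its reads from those of Amy-d, a near-identical gene, is uncertain. The glucosidase gene tobi (target of brain insulin) rose from 18.4 CPM ± 3.21 in control to 424 CPM ± 66.3 in mutant larvae (n = 3 each; log2 fold change 4.52 ± 0.15, adjusted p = 6.97e-10). The maltase gene Mal-A3 rose from 211 CPM ± 8.68 to 1546 CPM ± 163 (2.88 ± 0.09, adjusted p = 1e-11). Of the 14 amylases and maltases, 10 were higher, 0 lower and 4 did not pass the test, and adjusted over the list alone the count was also 10. All of these but Mal-A7, 9 of the 10, kept their call with every library left out in turn. The list was called by camera (median log2 fold change 1.78, adjusted p = 9.16e-86), and remained so at adjusted p = 0.000103 with an estimated correlation.

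Digestive lipase genes went the same way in part: 7 of 13 were higher, 2 lower and 4 did not pass (7 and 2 adjusted over the list alone). The gastric lipase gene mag rose from 25.3 CPM ± 3.47 to 161 CPM ± 11.7 (n = 3 each; 2.67 ± 0.12, adjusted p = 2.18e-09). Lip3 rose from 1.81 CPM ± 0.55 to 10.3 CPM ± 2.00, and the lipase gene CG6295 fell from 167 CPM ± 13.2 to 59.5 CPM ± 11.4. The camera call of the list (adjusted p = 1.84e-11) was lost at adjusted p = 0.0559 with an estimated correlation. Digestive serine proteases did not move together. Of 27, 6 were higher, such as Jon25Biii (0.90 ± 0.11, adjusted p = 3.51e-05), 5 were lower, such as Jon99Ciii (-0.87 ± 0.11, adjusted p = 0.000149), and 16 did not pass (6 and 5 adjusted over the list alone; camera adjusted p = 0.982). Of these calls, 3 of the 6 higher and 3 of the 5 lower were kept with every library left out in turn.

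**Figure D2:**
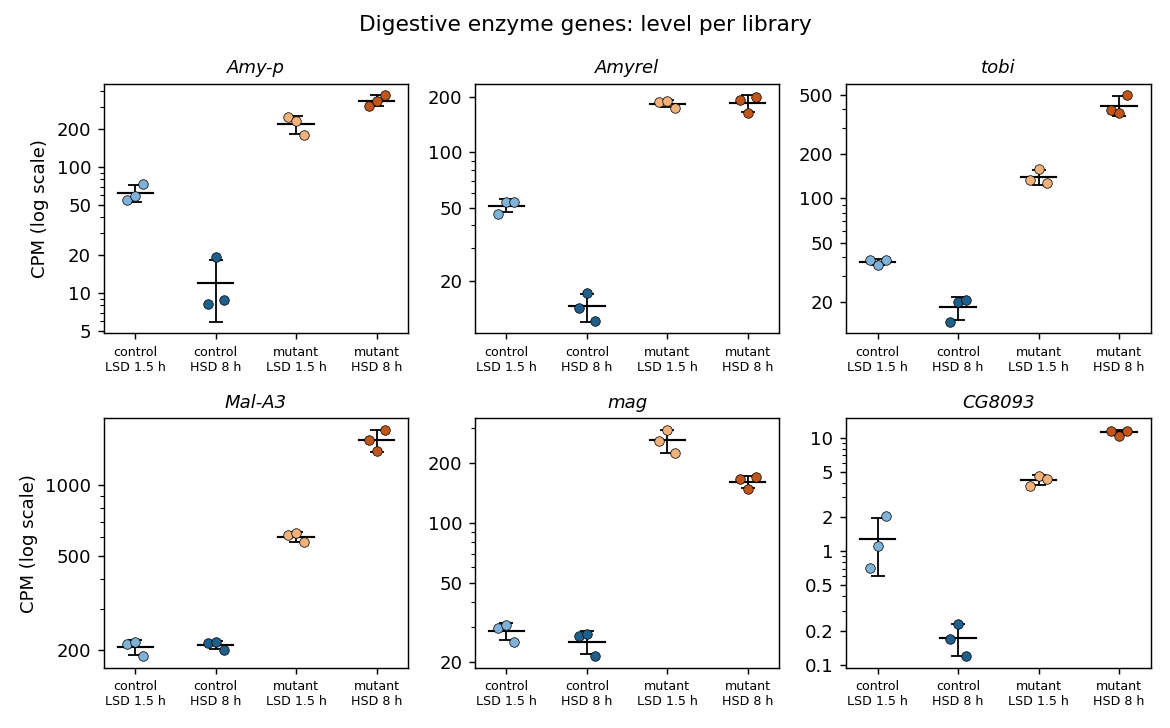
Level in CPM (y axis, log scale) of 6 digestive enzyme genes in each of the 12 libraries (points) by group (x axis), with bars for the mean and SD of 3 libraries. Amy-p falls from 62.4 to 12.1 CPM with diet in control larvae and stands at 220 and 337 CPM in mutant larvae.

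Genes of fatty acid synthesis were lower in mutant larvae on HSD. ACC, the acetyl-CoA carboxylase, stood at 2577 CPM ± 248 in mutant and 3902 CPM ± 153 in control larvae (n = 3 each; -0.60 ± 0.09, adjusted p = 0.000312). CG3523, the fatty acid synthase FASN1, stood at 7203 CPM ± 799 against 10399 CPM ± 508 (-0.53 ± 0.10, adjusted p = 0.00244). The desaturase gene desat1 differed by -0.42 ± 0.07 (adjusted p = 0.000508). Of 11 members, 0 were higher, 6 lower and 5 did not pass, and 8 were lower adjusted over the list alone. Of the 6, 5 kept their call with every library left out in turn. Camera called the list (median -0.40, adjusted p = 4e-05), and the call was lost at adjusted p = 0.056 with an estimated correlation. In the list of triglyceride synthesis and storage, 3 of 14 genes were higher, 1 lower and 10 did not pass (4 and 1 adjusted over the list alone). All 3 of the higher genes, CG1941 (2.22 ± 0.07, adjusted p = 2.22e-11), CG1942 (Dgat2; 2.31 ± 0.13) and CG1946 (1.91 ± 0.16), are diacylglycerol acyltransferase relatives. All 3 lie in 1 stretch of 2R (3597378 to 3604286), so a change of that region cannot be told from a change of the pathway. The lower gene, mdy (-0.41 ± 0.07, adjusted p = 0.000736), encodes another diacylglycerol acyltransferase. The list's median (-0.04) and its mean (0.42) differed in sign. Camera called the list higher (adjusted p = 4e-05), and the call was lost at adjusted p = 0.0559 with an estimated correlation.

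Genes of carbohydrate and amino acid metabolism were called in both directions. In glycogen and trehalose metabolism, 0 of 6 were higher, 4 lower and 2 did not pass (5 lower adjusted over the list alone; camera adjusted p = 0.000233, and adjusted p = 0.173 with an estimated correlation). UGP, which makes UDP-glucose, stood at -0.63 ± 0.09 (adjusted p = 0.000163) and the trehalose synthase gene Tps1 at -0.43 ± 0.07. In gluconeogenesis, 2 of 3 were lower, including fbp, the fructose-1,6-bisphosphatase (-0.35 ± 0.07, adjusted p = 0.00367; 2 adjusted over the list alone, camera adjusted p = 0.0389, and adjusted p = 0.338 with an estimated correlation). Of 13 glycolysis genes, 1 was higher, 1 lower and 11 did not pass (2 and 6 adjusted over the list alone; camera adjusted p = 0.0218, and adjusted p = 0.486 with an estimated correlation). The lower gene was Hex-C, a hexokinase (-1.36 ± 0.11, adjusted p = 5.95e-07). In amino acid catabolism, 4 of 14 were higher, 1 lower and 9 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.0806). Got2, an aspartate aminotransferase, stood at 0.78 ± 0.07 (adjusted p = 1.31e-06). In serine and one-carbon synthesis, 1 of 6 was higher, 3 lower and 2 did not pass (1 and 3 adjusted over the list alone; camera adjusted p = 0.28). CG6287, a phosphoglycerate dehydrogenase, stood at -0.53 ± 0.08 (adjusted p = 0.000226). Many of these calls were not kept with every library left out in turn. Those kept were 3 of the 4 lower in glycogen and trehalose metabolism, and in glycolysis 0 of the 1 higher and 1 of the 1 lower. In amino acid catabolism 2 of the 4 higher and 0 of the 1 lower were kept, and in serine and one-carbon synthesis 0 of the 1 higher and 2 of the 3 lower. The higher glycolysis gene, the enolase gene Eno, also lost its call with upper quartile scaling (adjusted p = 0.078), with estimates that were not robust (0.0538) and with the replicate letter as a block (0.0552). In the serine list, the higher gene CG3011 lost it with RLE scaling (adjusted p = 0.053), upper quartile scaling (0.0646) and no filter (0.0505). The lower gene aay lost it with the block (adjusted p = 0.0615), estimates that were not robust (0.059) and a fit of the 2 HSD groups alone (0.0517).

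Among 60 genes of xenobiotic metabolism, 15 were higher, 6 lower and 39 did not pass on HSD (17 and 12 adjusted over the list alone; camera adjusted p = 0.00248, and adjusted p = 0.351 with an estimated correlation). The glutathione S-transferase genes GstD3 (1.75 ± 0.11, adjusted p = 6.04e-08) and GstE1 (1.12 ± 0.08) were higher. The P450 gene Cyp28d2, which is not in this list, was lower (-2.71 ± 0.13, adjusted p = 4.89e-09). Of 7 sugar-responsive regulators, 3 were higher and 4 did not pass (3 adjusted over the list alone; camera adjusted p = 0.0723). Among the higher genes was the nuclear receptor gene Hnf4 (0.34 ± 0.06, adjusted p = 0.00269). Only this 1 of the 3 kept its call with every library left out in turn: without mutant HSD library C, Mio stood at adjusted p = 0.114 and daw at adjusted p = 0.103, and daw also lost its call with estimates that were not robust (0.0503). Of the xenobiotic calls, 13 of the 15 higher and 2 of the 6 lower were kept, and of the cuticle calls 0 of 1. The genes with the largest falls were CG14692, at 6.68 CPM ± 0.297 in mutant and 187 CPM ± 0.751 in control larvae (-4.81 ± 0.09, adjusted p = 6.58e-15) and CG15534, a sphingomyelinase relative (-3.00 ± 0.16, adjusted p = 2.41e-07). Among the genes with the largest rises, CG12951, a predicted serine protease, went from 1.11 CPM ± 0.405 to 46.1 CPM ± 6.21 (5.37 ± 0.18, adjusted p = 4.62e-11). The lipase gene CG8093 went from 0.175 CPM ± 0.058 to 11.1 CPM ± 0.636 (5.94 ± 0.33, adjusted p = 6.19e-09), a fold that rests on few reads in control larvae and on a gene with 25.7% of its exonic length in 1 exon only. Of the markers of other tissues and stages, cuticle proteins were called higher as a list with 1 of 71 called (0 adjusted over the list alone; 13 at an unadjusted p under 0.05, 3 by DESeq2; median 0.40, camera adjusted p = 0.000817, and adjusted p = 0.649 with an estimated correlation). Salivary gland genes were called lower as a list with 0 of 4 called by edgeR (3 lower adjusted over the list alone; 3 at an unadjusted p under 0.05, 3 by DESeq2; median -1.60, adjusted p = 0.039, and adjusted p = 0.288 with an estimated correlation). The 4 tested, ng1, ng2, ng3 and Sgs4, lie in 1 stretch of X (3134059 to 3145073). Over all 10284 genes, 824 were called (8%), 471 higher and 353 lower, of which 113 and 57 reached a 2-fold change. With the mean level of the cuticle genes as a covariate, 516 of these 824 calls were kept. With the test against a fold of 1.5, 145 were called. Of the genes named here Mal-A7, ACC, CG3523, desat1, mdy, Jon25Biii, Jon99Ciii, UGP, Tps1, fbp, Got2, CG6287, CG3011, aay, Eno, Mio, daw and Hnf4 did not pass it.

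The same comparison on the low sugar diet also placed digestive enzyme genes higher in mutant larvae. The lipase gene mag was at 260 CPM ± 34.2 in mutant and 28.6 CPM ± 2.89 in control larvae (n = 3 each; 3.18 ± 0.12, adjusted p = 1.43e-09). Lip3 stood at 20.7 CPM ± 3.57 and 2.51 CPM ± 0.397 (3.04 ± 0.21, adjusted p = 6.06e-07). Mal-A3 stood at 605 CPM ± 30.02 against 206 CPM ± 15.2 (1.55 ± 0.08, adjusted p = 1.44e-08), and Amyrel, an amylase relative, stood at 183 CPM ± 7.77 against 51.2 CPM ± 4.21 (1.84 ± 0.11, adjusted p = 8.64e-08). Of the 14 amylases and maltases, 9 were higher, 1 lower and 4 did not pass (10 and 1 adjusted over the list alone; median 1.11, camera adjusted p = 3.1e-34, and adjusted p = 0.00267 with an estimated correlation). Of the 13 lipases, 7 were higher and 6 did not pass (7 adjusted over the list alone; camera adjusted p = 5.93e-23, and adjusted p = 0.00593 with an estimated correlation). Of the 27 serine proteases, 10 were higher, 2 lower and 15 did not pass (13 and 3 adjusted over the list alone). Jon66Ci stood at 1.28 ± 0.13 (adjusted p = 5.94e-05), and the camera call of the list (adjusted p = 8.19e-07) was lost at adjusted p = 0.428 with an estimated correlation. The calls kept with every library left out in turn were 8 of the 9 higher and 0 of the 1 lower amylases and maltases, 7 of the 7 lipases, and 7 of the 10 higher and 1 of the 2 lower proteases. The lower maltase gene, CG14934, lost its call without control LSD library A (adjusted p = 0.0748) or B (0.0695) or mutant LSD library B (0.0632) or C (0.0871).

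In the triglyceride list on LSD, 5 of 14 genes were higher, 1 lower and 8 did not pass (5 and 2 adjusted over the list alone; camera adjusted p = 5.34e-06, and adjusted p = 0.032 with an estimated correlation). The higher genes again included CG1941 (1.12 ± 0.07, adjusted p = 9.53e-08) and CG1942 (1.36 ± 0.12, adjusted p = 4e-06), neighbours in 1 stretch of 2R. In fatty acid synthesis, only desat1 of the 11 tested genes was lower (-0.28 ± 0.07, adjusted p = 0.021), and ACC did not pass at -0.30 ± 0.09 (adjusted p = 0.0646). The call of desat1 was lost without control LSD library C (adjusted p = 0.0717) and without mutant LSD library A (0.0737), B (0.0518) or C (0.0855), and in a fit of the 2 LSD groups alone (0.058). The call of the list (camera adjusted p = 0.0301; 3 lower adjusted over the list alone) was also lost at adjusted p = 0.342 with an estimated correlation. Xenobiotic metabolism held 15 higher, 3 lower and 42 genes that did not pass (23 and 5 adjusted over the list alone; camera adjusted p = 1.24e-08, and adjusted p = 0.0951 with an estimated correlation). GstD3 stood at 1.88 ± 0.11 (adjusted p = 7.85e-08). Hex-C, of the glycolysis list (0 higher, 1 lower, 12 not passing; 2 lower adjusted over the list alone, camera adjusted p = 0.00628, and adjusted p = 0.428 with an estimated correlation), fell by 0.85 on the log2 scale (SE 0.11, adjusted p = 0.000108). With every library left out in turn, 4 of the 5 higher and 0 of the 1 lower triglyceride calls were kept, as were 11 of the 15 higher and 1 of the 3 lower xenobiotic calls.

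Few markers of other tissues passed on LSD. Salivary gland genes were lower as a list (1 of 4 called, 4 adjusted over the list alone; median -2.16, camera adjusted p = 2.71e-05, and adjusted p = 0.032 with an estimated correlation). As all 4 lie in 1 stretch of X, a change of that region cannot be told from a change of the tissue. The called member, ng1 (-2.36 ± 0.53, adjusted p = 0.0406), lost its call without control LSD library A (adjusted p = 0.0657), B (0.0791) or C (0.115) and without mutant LSD library A (0.125), B (0.12) or C (0.0713), with the replicate letter as a block (0.0529) and in a fit of the 2 LSD groups alone (0.0824). The related gene ng3 stood at -2.88 ± 0.71 (adjusted p = 0.0607) and ng2 at -1.97 ± 0.49 (adjusted p = 0.0621). Haemocyte markers held 2 higher genes of 7 (3 adjusted over the list alone; camera adjusted p = 0.0125, and adjusted p = 0.371 with an estimated correlation). Hml, which encodes hemolectin, was higher (0.42 ± 0.08, adjusted p = 0.00433). The other, Pxn, lost its call without control LSD library A (adjusted p = 0.0802) or C (0.0925) or mutant LSD library B (0.0567) or C (0.0685). Neuron markers held 1 lower gene of 10 (5 adjusted over the list alone; camera adjusted p = 0.00118, and adjusted p = 0.428 with an estimated correlation). That gene, Syt1, lost its call in a fit of the 2 LSD groups alone (adjusted p = 0.0657) and without control LSD library A (0.0578) or C (0.113) or mutant LSD library A (0.108) or C (0.121). Of the cuticle proteins, 0 of 71 were called by edgeR (0 adjusted over the list alone; 8 at an unadjusted p under 0.05, 3 by DESeq2; median 0.35, camera adjusted p = 0.0301, and adjusted p = 0.774 with an estimated correlation). Among the largest falls were CG14692, from 252 CPM ± 7.69 to 5.15 CPM ± 0.66 (-5.61 ± 0.09, adjusted p = 1.1e-15), and Rootletin, a cilium rootlet gene, from 43.1 CPM ± 2.38 to 10.5 CPM ± 0.915 (-2.04 ± 0.09, adjusted p = 1.43e-09). Over all genes, 535 were called (5.2%), 335 higher and 200 lower, so that 62.6% were higher. With upper quartile scaling 52% of 548 calls were higher. With the test against a fold of 1.5, 89 were called, and ng1, desat1, Hex-C, Hml, Pxn, Syt1 and CG14934 did not pass it.

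The effects of the genotype on the 2 diets, which share no library, overlapped. Of the genes higher in mutant larvae, 214 were called on both diets, where 15.3 would be expected from independent lists (Fisher's exact test, p = 4.57e-219), and of those lower, 105, with 6.9 expected (Fisher's exact test, p = 6.41e-104). Of the 322 genes called on both diets, 3 went in opposite directions. With the test against a fold of 1.5, 65 genes were called in the same direction on both diets.

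Genes beside sug were lower in mutant larvae on both diets. A run of 15 neighbours from Cyp9h1 to Psc (2R, 8728318 to 8868499, 140.2 kb in the deposited table) had a median log2 fold change of -0.71 on HSD (range -1.10 to 0.09) and -0.79 on LSD (range -1.21 to 0.06), with 13 and 14 of the 15 called lower. The ends of the run were set from these same fold changes, averaged over the diets. The run includes Aats-asp, an aspartyl-tRNA synthetase (-0.95 on HSD), Mdr49, a membrane transporter (-1.10), and Psc, a Polycomb group gene (-0.50), all placed by position rather than by the naming rule and so chosen after their values were seen. The mutant genotype carries the chromosome Df(2R)Exel7123, which the labels call a deficiency for sug, and its ends are not given in the sources used here. The other 72 genes within 500 kb had medians of -0.02 on HSD and 0.02 on LSD, with 4 and 3 called. Without the genes of the run, 810 genes were called on HSD and 520 on LSD.

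**Figure D3:**
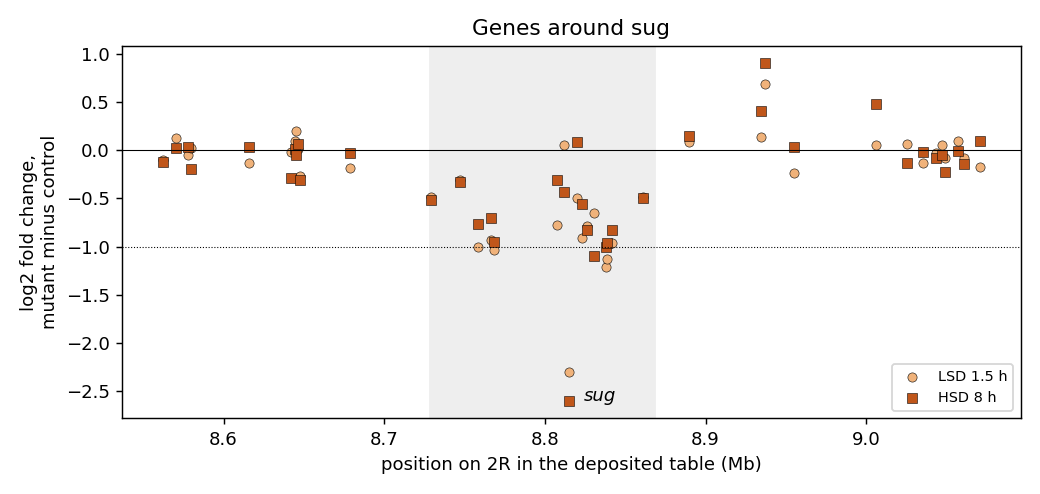
Log2 fold change of mutant against control (y axis) by position on chromosome arm 2R in Mb (x axis) for genes around sug, on LSD (circles) and HSD (squares), with the run from 8728318 to 8868499 shaded. Genes in the shaded run lie mostly between 0 and the dotted line at -1, with sug at -2.30 and -2.61.

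The next comparison asked how control larvae on HSD at 8 h differed from those on LSD at 1.5 h. Genes of fatty acid synthesis rose. AcCoAS, the acetyl-CoA synthetase, went from 177 CPM ± 14.2 to 950 CPM ± 29.1 (n = 3 each; 2.42 ± 0.09, adjusted p = 5.44e-11), ACC from 1007 CPM ± 71.4 to 3902 CPM ± 153 (1.96 ± 0.09, adjusted p = 7.23e-10), and desat1 from 1165 CPM ± 80.7 to 3694 CPM ± 99.8 (1.66 ± 0.07, adjusted p = 2.03e-10). Of 11 members, 8 rose, 1 fell and 2 did not pass (8 and 1 adjusted over the list alone; camera adjusted p = 5.34e-17, and adjusted p = 0.00476 with an estimated correlation). The member that fell was SCAP, an activator of the sterol response factor SREBP (-0.37 ± 0.06, adjusted p = 9.8e-05). In the pentose phosphate and NADPH list, 6 of 9 rose and 3 did not pass (6 adjusted over the list alone; camera adjusted p = 3.7e-11, and adjusted p = 0.0461 with an estimated correlation). Zw, the glucose-6-phosphate dehydrogenase (1.83 ± 0.09, adjusted p = 7.92e-10), and the malic enzyme gene Men rose (1.29 ± 0.07, adjusted p = 6.26e-09).

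Genes of ribosome biogenesis and amino acid breakdown fell in control larvae. All 10 ribosome biogenesis genes tested fell (10 adjusted over the list alone; camera adjusted p = 2.04e-10, and adjusted p = 0.146 with an estimated correlation). Fib, encoding fibrillarin, fell from 655 CPM ± 50.7 to 316 CPM ± 56.1 (-1.05 ± 0.11, adjusted p = 3.38e-06). In amino acid catabolism, 7 of 14 fell and 7 did not pass (7 adjusted over the list alone; camera adjusted p = 7.91e-05, and adjusted p = 0.132 with an estimated correlation). Oat, the ornithine aminotransferase, fell (-0.89 ± 0.11, adjusted p = 1.16e-05). In glycogen and trehalose metabolism, 5 of 6 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.117 with an estimated correlation). The glycogen branching enzyme gene CG33138 stood at 1.45 ± 0.08 (adjusted p = 7.86e-09). In glycolysis, 8 of 13 rose, 2 fell and 3 did not pass (8 and 2 adjusted over the list alone; camera adjusted p = 0.00237, and adjusted p = 0.263 with an estimated correlation). Pgi, the phosphoglucose isomerase, stood at 1.00 ± 0.07 (adjusted p = 9.43e-08). In the triglyceride list, 7 of 14 rose, 1 fell and 6 did not pass (8 and 2 adjusted over the list alone; camera adjusted p = 0.000358, and adjusted p = 0.117 with an estimated correlation). The glycerol-3-phosphate dehydrogenase gene Gpdh stood at 1.54 ± 0.06 (adjusted p = 2.76e-10). With every library left out in turn, 6 of the 8 rises in glycolysis and 0 of the 1 fall in the triglyceride list were kept.

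Digestive genes split in control larvae. Of 27 serine proteases, 23 rose and 4 did not pass (23 adjusted over the list alone; camera adjusted p = 3.99e-11, and adjusted p = 0.195 with an estimated correlation). An example is lambdaTry, a trypsin relative (1.32 ± 0.08, adjusted p = 1.83e-08). Of the 14 amylases and maltases, 5 rose, 4 fell and 5 did not pass (5 and 4 adjusted over the list alone; camera adjusted p = 0.00862, and adjusted p = 0.263 with an estimated correlation). Amy-p fell from 62.4 CPM ± 9.52 to 12.1 CPM ± 6.21 (-2.36 ± 0.31, adjusted p = 0.000321) and Amyrel by 1.82 on the log2 scale (SE 0.12, adjusted p = 3.69e-08). The maltase gene Mal-A7 rose from 4.85 CPM ± 0.596 to 38.6 CPM ± 1.16 (2.99 ± 0.10, adjusted p = 5.44e-11). Of 13 lipases, 1 rose, 5 fell and 7 did not pass (1 and 5 adjusted over the list alone; camera adjusted p = 0.035, and adjusted p = 0.379 with an estimated correlation). Of 7 sugar-responsive regulators, 5 rose, 1 fell and 1 did not pass (5 and 1 adjusted over the list alone; camera adjusted p = 0.00792, and adjusted p = 0.127 with an estimated correlation). The gene of the sugar sensor Mio (Mondo) stood at 0.78 ± 0.09 (adjusted p = 3.74e-06) and Spargel, a PGC-1 relative, fell (-1.03 ± 0.10, adjusted p = 2.5e-06). Leaving out every library in turn kept 18 of the 23 protease calls and 4 of the 5 falls among lipases. Over all genes, 4094 were called (39.8%), 1829 higher and 2265 lower on HSD. Changes of at least 2-fold were seen in 249 and 264, and 615 were called with the test against a fold of 1.5, which SCAP and Mio did not pass.

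**Figure D4:**
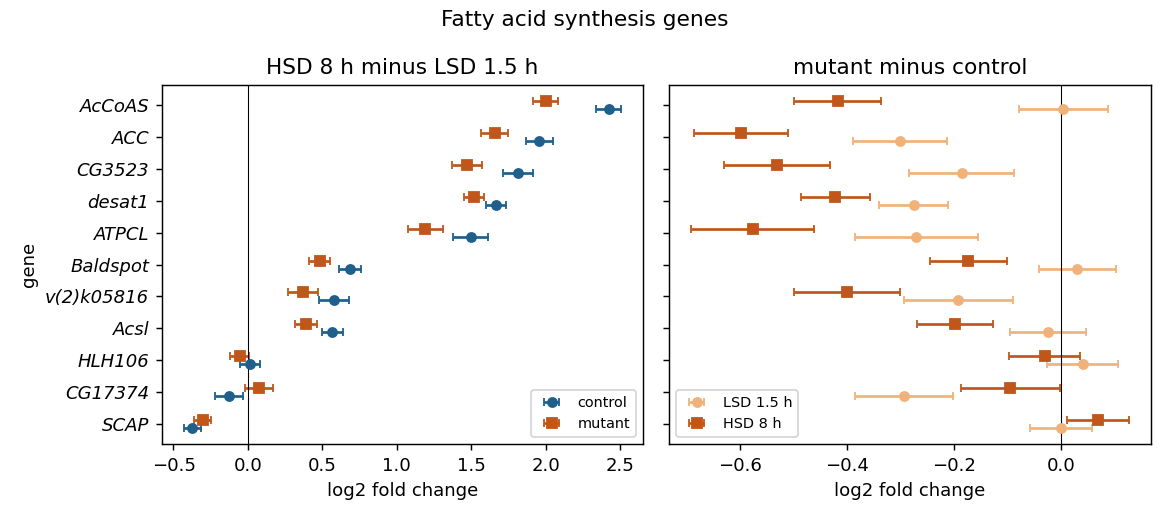
Log2 fold change (x axis) with its SE (bars) of the 11 fatty acid synthesis genes (y axis), for HSD at 8 h minus LSD at 1.5 h in each genotype (left) and for mutant minus control on each diet (right). AcCoAS rises by 2.42 in control and 2.00 in mutant larvae.

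Genes of fatty acid synthesis, NADPH supply and ribosome biogenesis also changed with diet in mutant larvae. AcCoAS rose from 178 CPM ± 17.4 to 711 CPM ± 48.2 (n = 3 each; 2.00 ± 0.09, adjusted p = 5.61e-10). In the fatty acid synthesis list 8 of 11 rose, 1 fell and 2 did not pass (8 and 1 adjusted over the list alone; camera adjusted p = 6.65e-11, and adjusted p = 0.0149 with an estimated correlation). In the pentose phosphate and NADPH list, 7 of 9 rose and 2 did not pass (7 adjusted over the list alone; camera adjusted p = 4.31e-11, and adjusted p = 0.032 with an estimated correlation). Zw stood at 1.87 ± 0.09 (adjusted p = 1.02e-09). Of 10 ribosome biogenesis genes, 9 fell and 1 did not pass (9 adjusted over the list alone; camera adjusted p = 3.26e-08, and adjusted p = 0.21 with an estimated correlation). Nop56, a box C/D particle gene, stood at -1.18 ± 0.12 (adjusted p = 2.72e-06). Among 7 heat shock genes tested, 1 rose, 3 fell and 3 did not pass (1 and 3 adjusted over the list alone; camera adjusted p = 0.053). Hsp83, a cytosolic chaperone gene, fell from 5379 CPM ± 90.5 to 1920 CPM ± 314 (-1.49 ± 0.13, adjusted p = 7.18e-07). Of the 14 amylases and maltases, 9 rose, 0 fell and 5 did not pass (9 adjusted over the list alone; median 1.27, camera adjusted p = 1.38e-19, and adjusted p = 0.0149 with an estimated correlation). Tobi rose from 140 CPM ± 16.6 to 424 CPM ± 66.3 (1.60 ± 0.13, adjusted p = 1.06e-06), and Mal-A3 from 605 CPM ± 30.02 to 1546 CPM ± 163 (1.35 ± 0.08, adjusted p = 1.66e-08). Amy-p (0.61 ± 0.28, adjusted p = 0.102) and Amyrel (0.01 ± 0.11, adjusted p = 0.952) did not pass. Of 13 lipases, 2 rose, 8 fell and 3 did not pass (2 and 8 adjusted over the list alone; camera adjusted p = 0.00991, and adjusted p = 0.294 with an estimated correlation). Of 27 serine proteases, 12 rose, 0 fell and 15 did not pass (11 adjusted over the list alone; camera adjusted p = 0.000481, and adjusted p = 0.47 with an estimated correlation). Leaving out every library in turn kept 10 of these 12 rises, 7 of the 8 falls among lipases and 2 of the 3 among heat shock genes. Over all genes, 4926 were called (47.9%), 2268 higher and 2658 lower, so that 46% were higher. With upper quartile scaling 51.4% of 4916 calls were higher, which turns the majority. Changes reached 2-fold in 301 and 318, and 749 were called with the test against a fold of 1.5.

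Some markers of neurons and salivary glands rose with diet in mutant larvae. Of 10 neuron markers, 6 rose, 0 fell and 4 did not pass (6 adjusted over the list alone; camera adjusted p = 0.0821), such as VGlut, a glutamate transporter gene (0.34 ± 0.07, adjusted p = 0.000848), and 3 of the 6 kept their call with every library left out in turn. Of the 4 salivary gland genes in 1 stretch of X, 3 rose and 1 did not pass (4 adjusted over the list alone; camera adjusted p = 0.0884), among them the glue gene Sgs4, from 0.235 CPM ± 0.145 to 0.775 CPM ± 0.18 (n = 3 each; 1.70 ± 0.48, adjusted p = 0.00785), a fold that rests on few reads. The call of ng2 (1.56) was lost without mutant HSD library A (adjusted p = 0.0757) or B (0.0596) or mutant LSD library A (0.0823) or B (0.0855). That of ng1 (1.55) was lost without mutant HSD library A (0.101), B (0.0854) or C (0.06), without mutant LSD library A (0.0947) or B (0.117), and with no filter (0.0537). VGlut and Sgs4 did not pass the test against a fold of 1.5. In control larvae, 1 of the 10 neuron markers fell, a call not kept with every library left out, and 0 of the 4 salivary gland genes were called (0 at an unadjusted p under 0.05, 0 by DESeq2). The control means of all 4 salivary gland genes were still higher on HSD, with a wide spread between libraries. For ng1 they were 29.4 CPM ± 8.64 on LSD and 58.6 CPM ± 31.9 on HSD, and for ng3 63.2 CPM ± 28.4 and 158 CPM ± 102. The interaction test of edgeR called 0 members of either list (4 and 0 at an unadjusted p under 0.05, 0 and 0 by DESeq2). Camera called the neuron list in the interaction (adjusted p = 0.00981, and adjusted p = 0.673 with an estimated correlation) and not the salivary gland list (adjusted p = 0.123).

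The diet responses of the 2 genotypes, which share no library, were compared directly. Of the genes called in both, 1471 rose in both (403.4 expected from independent lists), 1943 fell in both (585.4 expected), and 18 of 3432 went in opposite directions. With the test against a fold of 1.5, 451 genes were called in the same direction in both. Over 5749 genes with an average response past the threshold, the median response in its own direction was a log2 change of 0.37 in control and 0.42 in mutant larvae, a difference of 0.06 with a jackknife SE of 0.06, no larger than its error. Over the 100 genes with the smallest p the difference was -0.06, the opposite sign.

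**Figure D5:**
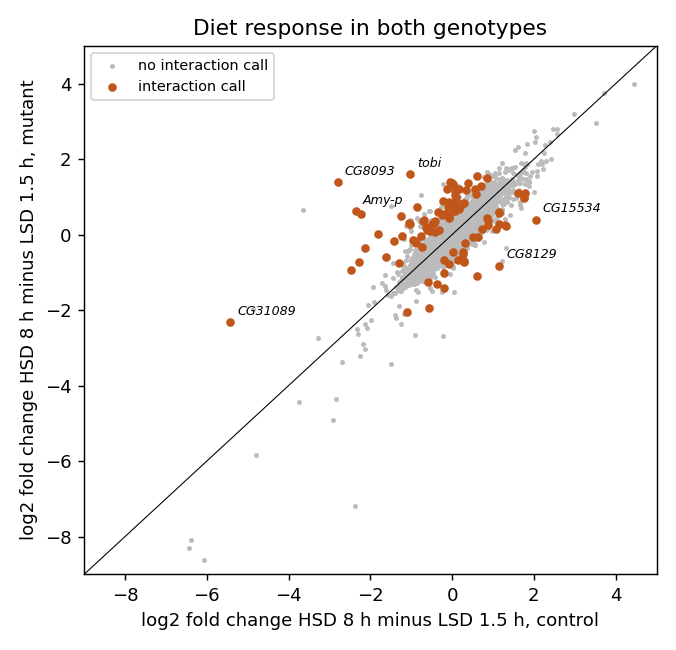
Log2 fold change of HSD at 8 h minus LSD at 1.5 h in mutant larvae (y axis) against control larvae (x axis), 1 point per gene of at least 4 CPM, with genes called by the interaction test in orange and a line of equal response. Most called genes lie above the line, with tobi at -1.02 in control and 1.60 in mutant larvae.

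The interaction test asked which genes responded differently to diet in the 2 genotypes. Amylases and maltases led it. Of 14, 7 had a higher response in mutant larvae, 0 a lower one and 7 did not pass (10 adjusted over the list alone; median 0.76, camera adjusted p = 1.67e-46, and adjusted p = 0.00078 with an estimated correlation). Tobi fell by 1.02 on the log2 scale in control and rose by 1.60 in mutant larvae (difference 2.62 ± 0.19, adjusted p = 2.82e-05). For Mal-A3 the response was 0.03 in control larvae, where it did not pass (adjusted p = 0.8), and 1.35 in mutant larvae (difference 1.32 ± 0.12, adjusted p = 2.82e-05). Among the lipases, CG8093 (4.19 ± 0.47, adjusted p = 0.000217) had a higher response in mutant larvae and CG6295 (-1.23 ± 0.17, adjusted p = 0.00226) a lower one. Of 13 lipases, 1 was higher, 3 lower and 9 did not pass (2 and 4 adjusted over the list alone; median -0.11, mean 0.36, of opposite sign; camera adjusted p = 0.551). Leaving out every library in turn kept 6 of the 7 amylase and maltase calls and 1 of the 3 lower lipase calls. CG8129, a serine racemase gene, rose by 1.16 in control larvae and fell by 0.82 in mutant larvae (difference -1.98 ± 0.20, adjusted p = 0.000217).

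Of the 11 fatty acid synthesis genes, 0 passed the interaction test of edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2): AcCoAS stood at -0.42 ± 0.12 (adjusted p = 0.139), CG3523 at -0.35 ± 0.14 (adjusted p = 0.394) and ACC at -0.30 ± 0.12 (adjusted p = 0.42). Adjusted over the list alone, 1 was lower, and the camera call (median -0.20, adjusted p = 0.00981) was lost at adjusted p = 0.312 with an estimated correlation. Serine proteases (0 of 27 called by edgeR, 5 lower adjusted over the list alone, 11 at an unadjusted p under 0.05, 2 by DESeq2; median -0.26, camera adjusted p = 1.91e-07) likewise lost their call at adjusted p = 0.451 with an estimated correlation. Of 10284 genes, 102 were called, 68 with a higher and 34 with a lower response in mutant larvae. Among the 68, 24 were called as rising in mutant larvae with no call in control larvae, 16 as falling in control larvae with no call in mutant larvae, and 13 fell in control and rose in mutant larvae. Without mutant LSD library C, 67 genes were called, DESeq2 called 173, and the test against a fold of 1.5, which CG6295 did not pass, called 15.

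Genes that rose with diet in control larvae were compared with those lower in mutant larvae on HSD. These comparisons share the control HSD libraries, so chance alone pushes their fold changes apart. Across 8207 genes, the correlation of the fold changes was -0.116 where 10 simulations without effects gave a mean of -0.492, and the covariance was -0.0219 where the simulations gave -0.0147. Of the genes lower in mutant larvae, 136 (38.5%) had risen with diet in control larvae, with 62.8 expected from independent lists, and of those higher, 131 (27.8%) had fallen, with 103.7 expected. Genes higher in both numbered 129 (83.8 expected) and lower in both 74 (77.7 expected). The simulations, which hold no effects, gave at most 0 shared calls, which is no measure for overlaps between comparisons that hold effects. Part of the excess may come from the shared control libraries, which are too few to split.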

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

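The counts of other splits and the test with the cuticle genes as a covariate were set out before their results were seen, while the tests on serine proteases and on chromosome arms were chosen after the result was seen.

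Of the 199 named genes, 29 had a diet response that differed between the genotypes by the interaction test (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among digestive carbohydrate enzymes, the difference of mutant minus control log2 responses was 2.97 for Amy-p, 2.77 for Amy-d, 2.62 for tobi, 1.83 for Amyrel, 1.32 for Mal-A4, 1.32 for Mal-A3 and 0.97 for Mal-A2, with reads of Amy-p and Amy-d hard to tell apart. The call of Amy-d was lost with the letters as a replicate block (adjusted p = 0.0874) and without any 1 of the libraries except control HSD B (adjusted p = 0.053 to 0.0955). Among lipases it was 4.19 for CG8093, -0.58 for CG6296, -0.92 for CG17191 and -1.23 for CG6295. For CG6296 the call was lost without any 1 of the libraries except control LSD C and control HSD C (adjusted p = 0.0502 to 0.112), with the replicate block (0.0794) and with estimates that were not robust (0.0634). For CG17191 it was lost with the replicate block (0.104) and without any 1 of the libraries except control LSD B, mutant HSD A and mutant LSD A (adjusted p = 0.053 to 0.0995). The predicted serine protease gene CG12951 had a difference of 1.74, and the acyltransferase relatives CG1941 and CG1942 of 1.11 and 0.95. That of CG31089 was 3.11 and rests on few reads in control larvae on HSD (mean 0.136 CPM). Other positive differences were 1.29 for Sodh-1 (sorbitol dehydrogenase), 1.2 for CG12262 (medium-chain acyl-CoA dehydrogenase), 0.99 for Rootletin, 0.82 for v (tryptophan dioxygenase), 0.8 for CG14692, 0.56 for sut1 (a sugar transporter) and 0.56 for Cyp6d5. The call of sut1 (adjusted p = 0.0397) was not kept with every library left out in turn. Negative differences were -0.8 for GstE7, -1.1 for Ugt86Dh, -1.38 for CG13078, -1.64 for CG15534, -1.69 for Cyp28d2 and -1.98 for CG8129. For CG6287 (-0.55) the call was lost without control HSD B (adjusted p = 0.0577), control LSD A (0.0651), mutant HSD B (0.0581) or mutant LSD C (0.0528), and for Ugt86Dh without any 1 of the libraries except control LSD C, mutant HSD C and mutant LSD B (adjusted p = 0.052 to 0.104).

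Many amylase, maltase and digestive lipase genes were higher in mutant larvae on both diets, but 2 of 13 lipases were lower on HSD, where their list call was lost with an estimated correlation (adjusted p = 0.0559), and 1 of 14 amylases and maltases, CG14934, was lower on LSD, a call lost without control LSD A (adjusted p = 0.0748) or B (0.0695) or mutant LSD B (0.0632) or C (0.0871). More gut RNA in the mutant libraries would raise digestive serine proteases alike. Their upper quartile was 0.227 on HSD and 0.508 on LSD, where the median of amylases and maltases was 1.777 and 1.112. These values speak only to more gut RNA as the whole cause. The protease median was -0.095 on HSD but 0.247 on LSD, with 10 called higher and 2 lower on LSD. More gut RNA as a part of the cause therefore stays open. With the level of the cuticle genes as a covariate, the HSD median of amylases and maltases stayed at 1.747 with 9 of 14 called. For amylases and maltases on HSD, this argues against the trend the cuticle genes follow as the whole cause. The 7 lipases called higher on HSD lie on 3 chromosome arms (1 on 2R, 1 on 3L and 5 on 3R). This argues against variants on 1 arm that act only on genes of that arm as their whole cause. It cannot speak to a variant that acts on genes of other arms. The lipase genes CG6296, CG6295, CG17191, CG6283 and CG6271 lie in 1 stretch of 3R (22828958 to 22851831). On HSD, the means of CG6296, CG6283 and CG6271 were higher in mutant larvae and those of CG6295 and CG17191 lower. For the genes of this stretch, variants linked on 3R stay open. The 10 amylases and maltases lie on 2 arms, 9 on 2R, the arm of the deletion, and 1 on 3R. The maltase genes from Mal-A1 to Mal-A8 lie in 1 stretch of 2R (4337169 to 4361466). For amylases and maltases, variants linked on 2R therefore stay open, and for all of these genes so do loss of sug, loss of its deleted neighbours and the genetic background, none of which was tested apart.

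The numbers of called genes were 824 and 535 for the genotype on HSD and LSD, and 4094 and 4926 for diet in control and mutant larvae, and for each of these 1 of 10 splits, the real one, gave as many, with 0 genes in the highest other split. The splits of 3 against 3 libraries are too few for a share under 0.05. Each other split also mixes libraries of both true groups, which puts the real differences into the spread within groups. Few calls there were therefore likely in advance and are no measure of chance. For the interaction, 5 of 100 splits drawn gave at least the 102 genes of the real one, so chance cannot be excluded by this count. The highest, 1260, exchanges the genotypes on LSD alone and so equals the test of the average genotype effect, which points to the structure of the samples. The other 3, with 383, 237 and 143 genes, keep the 3 control HSD libraries together and set 1 control LSD library with 2 mutant LSD libraries, so they also carry part of the genotype effect.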

How the results depend on the processing

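The cuticle covariate and the overlaps under each setting were chosen after the data were seen, and the other settings were fixed before their results. Against a fold of 1.5, calls fell from 824 to 145 (genotype on HSD), 535 to 89 (genotype on LSD), 4094 to 615 (diet in control), 4926 to 749 (diet in mutant) and 102 to 15 (interaction), and shared calls in the same direction from 3414 to 451 for diet and from 319 to 65 for genotype, as this test asks for a larger change. DESeq2 called 173 genes for the interaction (the cause was not tested), and 915, 634, 3813 and 4612 in the other comparisons. With 1 library left out, the interaction called 67 (without mutant LSD C) to 113 genes, the genotype 556 to 857 on HSD and 358 to 501 on LSD, and diet 3440 to 4090 in control and 4165 to 4655 in mutant larvae, with fewer libraries in each fit. With upper quartile scaling, 52% of the LSD genotype calls were higher, against 62.6%, 50.8% of those on HSD, against 57.2%, and 51.4% of the diet calls in mutant larvae, against 46%. With the cuticle covariate, 581, 611, 4323, 4771 and 108 genes were called, in the order above. Of the genotype calls, 516 of 824 on HSD and 459 of 535 on LSD were kept with it. Of the diet calls, 4076 of 4094 in control and 4581 of 4926 in mutant larvae were kept, and 98 of 102 for the interaction. Named genotype calls lost on HSD included those of Mal-A7, Mio, daw, CG3011 and aay. The difference of median responses was -0.059 over the 100 genes with the smallest p, against 0.055, and the cause was not tested. With an estimated correlation, the lists called fell from 11 to 1 (genotype on HSD), 13 to 4 (genotype on LSD), 13 to 2 (diet in control), 13 to 3 (diet in mutant) and 8 to 1 (interaction), and the cause was not tested. Fry, which does not compare a list with other genes, called 20 lists for diet in control, 20 for diet in mutant and 2 for the interaction. The replicate letters were not used to pair the samples, as same-letter libraries did not all deviate together: their correlations ran from -0.62 to 0.57, and 3 of 12 libraries correlated best with their own letter. With the letter as a replicate block, 756, 485, 3961, 4842 and 83 genes were called. Of 340 called pairs of a named gene and a comparison, 0 changed sign under the settings run for them, and 301 kept their call under those settings other than the fold of 1.5. DESeq2 gave values for 339 pairs, the strict filter for 328 and fits to the groups of 1 comparison for 319. Calls were lost for 38 pairs with some library left out, 9 with the block, 16 with the covariate and 139 against a fold of 1.5. Among values that did not pass, Mal-A3 with diet in control larvae ran from -0.017 to 0.072 and Amyrel with diet in mutant larvae from -0.028 to 0.094 (-0.017 without mutant HSD A and -0.026 without mutant LSD C) with 1 library left out, both around 0. Depth limits genes of few reads, such as CG8093 at 0.175 CPM in control larvae on HSD.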

Other observations

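The tests on the genes beside sug and on the variation within groups were chosen after the result was seen.

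Of the 15 genes around sug, 13 were called lower in mutant larvae on HSD and 14 on LSD. CG13319 was called on neither diet. Over both diets, the log2 fold changes of the 15 had a median of -0.81. The run was delimited from these values, by the highest sum over neighbouring genes of the fall in log2 units (at most 1.5 a gene) minus 0.4, with sug set to 0. It scored 4.42 and the highest run elsewhere in the genome 3.49, which is consistent with the loss of 1 copy under the deletion. If the sug protein itself raised its neighbours, their difference would be larger on HSD, where sug is higher, but the median interaction was 0.135. The SE of 0.075 is that of a mean over the 15 genes, taken as independent, so it is only a rough guide. By it, the median lay within 2 standard errors of 0. NAT1 (0.46, adjusted p = 0.0169) and CG17019 (0.59, adjusted p = 0.00959) passed edgeR's interaction test. NAT1 was less reduced on HSD (-0.31) than on LSD (-0.78). CG17019 was not reduced on HSD (0.09, adjusted p = 0.558 by edgeR) and stood at -0.5 on LSD. The interactions of CG13319 (-0.49) and Mdr49 (-0.44) went the other way. Regulation by the sug protein cannot be told apart from no effect with these libraries.

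Libraries of the same group differed along 1 main axis, which held 49.5% of the variance within groups over 8207 genes. Of the 200 genes leading it, 31 were in the lists of cuticle proteins and ecdysone response, where 1.51 were expected (20.52 times as many; Fisher's exact test, p = 2.22e-34). The test was run because cuticle genes had been seen to vary, so it restates that observation and does not test its cause. Different points of the moult cycle may account for it, which stays open. Replicate letters explained a share of 0.24 of the axis, and 0.407 of 216 permutations of the letters explained as much, so a batch shared by libraries of 1 letter cannot be told apart from no batch with so few libraries.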
